A study of Mus musculus with 4 samples.

How the data were processed

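RNA was measured in 4 libraries of sorted tumour MDSCs, 2 from WT and 2 from Trem2 mutant donors. Per the labels, recipients were 6 weeks old, MDSCs were injected 4 weeks after the tumour challenge, and tumours were taken 6 h later and digested for 45 minutes before sorting. Per the labels' protocols, ribosomal RNA was depleted from total RNA and libraries were run on a NextSeq instrument. Genes of noncoding classes and of the mitochondrial chromosome together took 6.77% and 5.26% of reads in WT 1 and WT 2. They took 20.7% in Trem2 mutant 1, where Gm42418 alone took 13.9%, and 7.63% in Trem2 mutant 3.

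The deposited values are raw counts of reads per Ensembl gene, whole numbers with no normalization. Per the submitters' processing notes, FastQC, STAR 2.5.2a and DESeq2 were used with the build GRCm38 (mm10). The read counter, its strand setting and the annotation release are not given in the sources used here. The table held 17476 genes and no gene with fewer than 11 reads in all, so genes below that were not analysed here. Of the IDs, 17422 matched GENCODE M21, the annotation used for names, classes and positions, and 54 did not. The columns carry the numbers 1 and 2 for WT and 1 and 3 for the mutant; the number 3 matches no label number, so that column was used as a mutant library with no number of its own. Scaled by library totals, library pairs of a genotype differed by more than sampling noise (median squared difference relative to noise 2.01 within WT and 6.24 within mutant). Each was therefore counted as a separate library, though this does not show that they came from separate animals or cultures. The mutant value includes the shift in other genes from the reads that Gm42418 took in Trem2 mutant 1.

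The counts were analysed with R 4.3.3 and edgeR 4.0.16. Genes were filtered with filterByExpr, leaving 14239, and scaled with TMM. The quasi-likelihood test (glmQLFit in its default form, glmQLFTest, two-sided) compared mutant with WT, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. The default form was settled after the counts of calls under both forms had been seen, and the bias-adjusted form was added as an alternative. The common biological coefficient of variation was 0.106. With 2 residual degrees of freedom and 5.71 prior degrees of freedom, most of the precision came from sharing the spread across genes. Standard errors are the log2 fold change divided by the root of the F statistic. CPM are TMM-scaled, with means and SDs over 2 libraries. A floor of 3 counts corresponded to 0.291 to 0.373 CPM in the single libraries, and floors and count intervals (95%) cover counting error only.

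The design, the alternatives, the rule for named genes and 45 gene lists were fixed before the data were examined. Lists share members, such as complement component genes in both the complement and the macrophage list. Lists with at least 5 tested members, 42 in all, were tested with camera (limma 3.58.1) at a preset correlation of 0.01. They were tested again with an estimated correlation, and with fry. With an estimated correlation, camera uses the 2 residual degrees of freedom, so few lists could pass whatever their correlation. The lists of T and NK cell markers (4 tested), epithelial markers (4 tested) and genes disrupted in NRG hosts (2 tested) were too small. Genes were named as follows: Trem2; the 12 largest log2 fold changes per direction among genes past the threshold with a mean of at least 5 CPM, no overlap between groups and no predicted-gene name; and up to 4 members per list with the lowest p. The rule took 188 genes. From the list members, the examples in the text were picked after the values with 1 library left out had been seen, mostly among calls that held, so they are more stable than the rule genes as a whole. Outside this rule, Ddx3y and Eif2s3y complete the Y-linked genes, Kdm5c, Kdm6a, Eif2s3x and Ddx3x were set for a test before their values were seen, and Abcc10, Trerf1 and Gm42418 were chosen after their values were seen.

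Alternatives were other scalings (RLE, library totals alone, upper quartile), no filter or a stricter filter (at least 10 reads in 2 libraries and a mean of at least 1 CPM), DESeq2 1.42.0, limma-voom, leaving out 512 genes of noncoding and mitochondrial classes, at least a 2-fold change, and leaving out each library in turn. In the last case the lone library of a group was assumed to vary like the other group. On simulated counts for 14239 genes with 2 libraries per group, the edgeR test of mutant against WT recovered 67 of 98 genes changed 2-fold (68.4%) and 92 of 98 changed 4-fold (93.9%). Of 161 calls, 2 were on unchanged genes. The simulation gave both groups the same spread, taken from the trend over genes, and balanced the rises and falls. The data had unequal spread within the pairs and mostly higher calls, so these rates may be too favourable. In a separate simulation, 0 of 41 unshifted lists were called. Simulated genes were drawn independently of each other, so this does not test lists whose members vary together. The granule list, for example, had an estimated correlation of 0.925.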

Results

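The series asked which genes and pathways differ between myeloid-derived suppressor cells (MDSCs) carrying a mutated Trem2 gene and wild-type (WT) MDSCs. MDSCs are immature granulocytic and monocytic cells that restrain T cells. Trem2 encodes a lipid-sensing receptor of myeloid cells. Per the labels, the cells were grown from bone marrow of C57BL/6 or Trem2 mutant mice and given to male NRG mice, an immunodeficient strain lacking lymphocytes. The recipients carried subcutaneous tumours of TRAMP-C1, a mouse prostate cancer line. Cells positive for CD45, CD11b and GR1 were sorted from the tumours 6 h later, and the gate named no marker that separates injected cells from the recipient's own. There were 2 libraries per genotype, named here by the numbers in their column names: WT 1, WT 2, Trem2 mutant 1 and Trem2 mutant 3. Total counts were 8037733 and 8077966 reads for WT 1 and WT 2, and 10306674 and 9820893 reads for Trem2 mutant 1 and Trem2 mutant 3. Nothing in the labels says that the libraries came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical.

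Trem2 itself (ENSMUSG00000023992, GRCm38 chromosome 17, 48346401 to 48354147, plus strand) was lower in the mutant libraries. Its normalised read count (CPM) was 48.2 ± 5.69 in WT and 21.9 ± 1.36 in mutant libraries (SD, n = 2 each). The log2 fold change was −1.14 (SE 0.125, edgeR quasi-likelihood test, adjusted p = 0.00157). Reads over the gene numbered 406 and 477 in the WT libraries and 191 and 195 in the mutant libraries. The kind of Trem2 mutation is not given in the sources used here. A count over the whole gene does not show which part of the transcript the reads came from. As the gate did not separate injected from recipient cells, the share of these reads from recipient cells is not known.

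Beside Xist and Tsix, which are described with the sex-linked genes, genes of neutrophils and their granules made up most of the largest rises in the mutant libraries. Ltf (lactoferrin) was 98.7-fold higher, at 46.2 ± 6.97 CPM in WT and 4562 ± 1100 CPM in mutant libraries (SD, n = 2 each). Ngp rose 97.4-fold and Camp, the cathelicidin antimicrobial peptide, 73.4-fold. Itgb2l (54.4-fold), Stfa3 (30.5-fold), Ceacam10 (27.6-fold), Cd177 (26.0-fold), Chil3 (21.5-fold) and Ly6g (20.6-fold) also rose. Fcnb rose 48.3-fold, and its log2 fold change of 5.60 (SE 0.575) was 4.99 without Trem2 mutant 1. It had only 3 and 2 reads in WT 1 and WT 2, at or below the floor of 3 counts, so its fold is imprecise. Stfa3 belongs to a family of near-identical genes, so its share of reads is uncertain. The falls were smaller. Kdm5d, a Y-linked demethylase gene, was 6.70-fold lower, Stra6l 4.00-fold, Dusp4 3.82-fold, Tanc1 3.69-fold and Igf2bp2 3.16-fold. The lectin receptor genes Clec4a3 (3.16-fold) and Clec4a1 (2.92-fold), the transcription factor gene Bhlhe41 (2.76-fold), Y-linked Uty (2.68-fold), Wfdc17 (2.65-fold) and the cathepsin gene Ctsk (2.43-fold) were also lower. Gdf15 was 2.73-fold lower, and its call was lost without WT 1 and without WT 2, with log2 fold changes of −1.42 and −1.46. Its log2 fold change of −1.45 was −0.93 without Trem2 mutant 3 and −2.15 without Trem2 mutant 1.

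Of 14239 genes tested, 1360 were higher and 513 lower in the mutant libraries (edgeR quasi-likelihood test, adjusted p under 0.05), so 72.6% of the calls were higher. With library totals as the only scaling, 650 were higher and 4365 lower, so 13% were higher, and the median log2 fold change of all genes was −0.40 instead of −0.02. Among protein-coding genes, 1215 were higher and 459 lower. At least a 2-fold change was found for 497 higher and 95 lower genes. Without WT 1, 489 genes were higher and 92 lower, and without WT 2, 719 were higher and 129 lower. Without Trem2 mutant 3, 2090 were higher and 912 lower. Gm42418, a locus that overlaps ribosomal RNA sequence, took 13.9% of the reads of Trem2 mutant 1, against 1.04% in WT 1, 0.258% in WT 2 and 0.418% in Trem2 mutant 3.

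**Figure D1:**
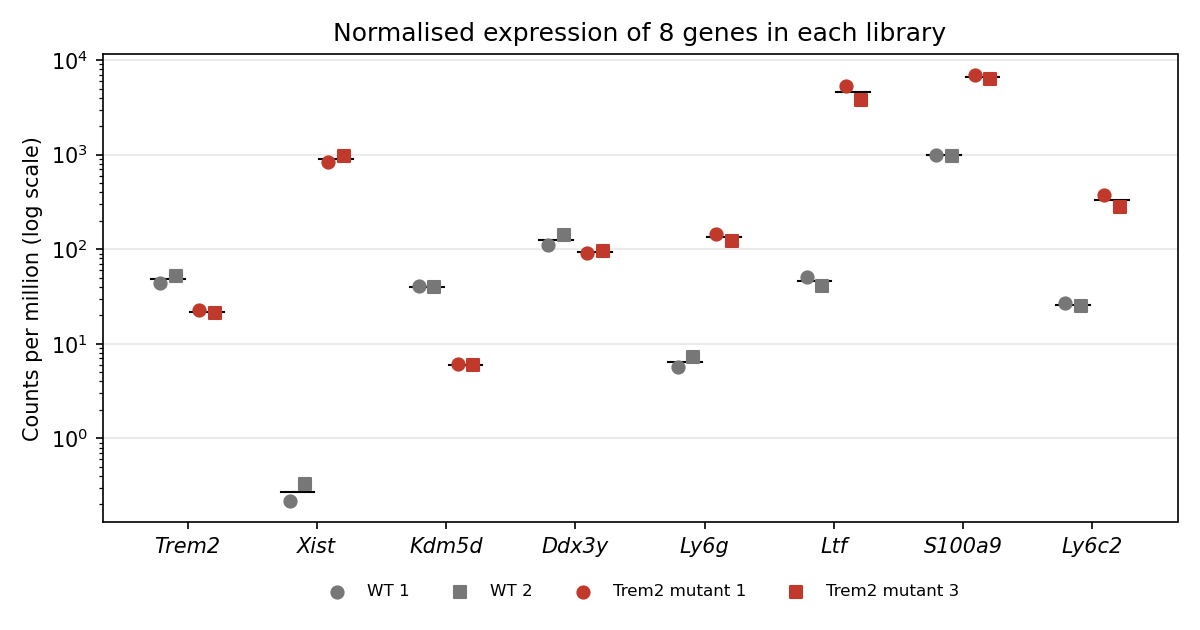
Normalised expression (CPM, log axis) of 8 genes in each of the 4 libraries, with a black line at the group mean. Ltf, S100a9, Ly6g, Ly6c2 and Xist lie higher in both mutant libraries, and Trem2 and Kdm5d lie lower; Ddx3y, with group means of 126 and 93.5 CPM, lies closer together.

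Both granulocyte lists rose in the mutant libraries. Of 18 measured genes of immature granulocyte granules, 15 rose and 0 fell (17 rose adjusted over the list alone), with a median log2 fold change of 2.12. The list was higher by camera, a test of a list against all other genes (adjusted p = 3.86e-65; adjusted p = 0.323 with an estimated correlation). Beside Ltf, Ngp and Camp, Ifitm6 rose 11.8-fold. Of 20 mature neutrophil markers, 16 rose and 0 fell (18 rose adjusted over the list alone), with a median of 0.97 (camera adjusted p = 1.47e-42; adjusted p = 0.323 with an estimated correlation). S100a9, a calcium-binding alarmin abundant in neutrophils, went from 981 ± 20.1 to 6601 ± 438 CPM (SD, n = 2 each), and Retnlg rose 8.35-fold. Under scaling by library totals alone, 14 granule genes rose and 0 fell, and 12 mature neutrophil markers rose and 1 fell.

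Eosinophil and fibroblast markers rose with the granulocyte genes. Of 8 eosinophil markers, 7 rose (7 adjusted over the list alone), among them Epx (5.32-fold) and Prg2 (5.95-fold), both eosinophil granule proteins. The list median was 2.42, or 2.42 with Ear1 at its bound (camera adjusted p = 1.93e-09; adjusted p = 0.323 with an estimated correlation). Ear1 had 0 reads in WT and 44 in the mutant libraries, at least 15.2-fold higher over a floor of 3 counts for the WT group, and it has near-identical relatives. Without WT 1, 3 eosinophil markers rose, and 3 rose without WT 2. Of 15 fibroblast and mural cell markers, 10 rose and 0 fell (12 rose adjusted over the list alone), with a median of 1.77 (camera adjusted p = 9.84e-15; adjusted p = 0.323 with an estimated correlation). The collagen genes Col1a2 and Col3a1 reached 143 ± 13.5 and 84.0 ± 4.06 CPM in the mutant libraries (SD, n = 2), from 41.8 ± 8.84 and 21.9 ± 5.61 CPM in WT. Of 5 erythroid markers, 3 rose and 1 fell (4 rose and 1 fell adjusted over the list alone), and the list did not pass (median 2.37, camera adjusted p = 0.0513). With an estimated correlation the list did not pass either (camera adjusted p = 0.527), and the passes given next are at the preset correlation. It passed without WT 1 (adjusted p = 0.0168, 1 rose), without WT 2 (1.94e-05) and without Trem2 mutant 1 (1.84e-08, 5 rose). It also passed with library totals as the only scaling (1.37e-05), upper-quartile scaling (0.0440) and no filter (0.0330).

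Of 6 sex-linked genes, 2 rose and 4 fell (2 rose and 4 fell adjusted over the list alone). Xist, the RNA that coats the inactive X chromosome of female cells, had 5 reads in WT and 16045 in the mutant libraries, a ratio of 3332 (95% interval 1427 to 10260, counting error only). Its antisense partner Tsix had 0 and 1460 reads, at least 505-fold higher over a floor of 3 counts for the WT group. As the use of strand in counting is not given in the sources used here, reads of this pair cannot be assigned with certainty. All 4 Y-linked genes of the list fell but stayed detected: Kdm5d (log2 fold change −2.74, SE 0.132), Uty (−1.42, SE 0.213), Eif2s3y (−0.68, SE 0.138) and Ddx3y (−0.43, SE 0.114). The calls of Eif2s3y and Ddx3y were lost without WT 2, leaving 2 falls, with Ddx3y at −0.26. Ddx3y was also lost without Trem2 mutant 1, with RLE scaling, with limma-voom and with DESeq2, leaving 3 falls in each. The list was higher by camera (adjusted p = 2.34e-05; adjusted p = 0.323 with an estimated correlation), with a mean of 3.15 (2.56 with Tsix at its bound) but a median of −0.55. With limma-voom the list did not pass, and its direction was reversed (adjusted p = 0.362). Xist and the Y-linked genes thus moved with genotype, as the granulocyte, eosinophil and fibroblast markers did.

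Monocyte genes rose less than granulocyte genes did by their medians, a difference that was not tested. Of 18 monocyte markers, 11 rose and 0 fell (12 rose and 1 fell adjusted over the list alone), with a median of 0.80 (camera adjusted p = 6.02e-09; adjusted p = 0.354 with an estimated correlation). Ly6c2, which with Ly6g encodes the antigens bound by GR1 antibodies, rose 12.8-fold, and Plac8 2.24-fold. Without WT 1, 4 monocyte markers rose, and 7 without WT 2. Of 17 macrophage markers, 5 rose and 0 fell (8 rose and 1 fell adjusted over the list alone), with a median of 0.85 (camera adjusted p = 0.00134; adjusted p = 0.517 with an estimated correlation). Fcgr1, the high-affinity IgG receptor, rose 1.83-fold. Without WT 1, 1 macrophage marker rose, and 11 rose without Trem2 mutant 3. Of 13 complement genes, 7 rose and 0 fell (8 rose and 1 fell adjusted over the list alone), led by Cd55 at 5.09-fold (median 0.89, camera adjusted p = 7.32e-05; adjusted p = 0.481 with an estimated correlation). Without WT 1, 2 complement genes rose. Scaled by library totals alone, 8 monocyte markers rose and 2 fell, 6 macrophage markers rose and 2 fell, and 6 complement genes rose and 2 fell. With DESeq2, 7 monocyte markers rose.

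Lists of migration, phagocytosis and matrix genes were higher relative to other genes. Granulocyte and fibroblast markers rose in the same libraries, so these lists and those described below may follow the make-up of the sort. Whether they moved apart from it was not tested. Of 19 chemokine receptor and adhesion genes, 10 rose and 0 fell (14 rose and 1 fell adjusted over the list alone), with a median of 0.55 (camera adjusted p = 1.07e-06; adjusted p = 0.363 with an estimated correlation). C5ar1, the receptor of complement fragment C5a, rose 1.96-fold and Ltb4r1, the leukotriene B4 receptor, 1.78-fold. Without WT 1, 4 of these genes rose, and 6 without WT 2. Of 19 phagocytic receptors, 5 rose and 1 fell (8 rose and 3 fell adjusted over the list alone), with Fcgr4 3.16-fold higher (median 0.41, camera adjusted p = 0.0136; adjusted p = 0.488 with an estimated correlation). Their list call was lost without Trem2 mutant 1 (adjusted p = 0.129, 2 fell), 2 genes rose without WT 1, and 10 without Trem2 mutant 3. Of 20 matrix remodelling and angiogenesis genes, 11 rose and 1 fell (13 rose and 3 fell adjusted over the list alone), with a median of 0.52 (camera adjusted p = 3.89e-05; adjusted p = 0.424 with an estimated correlation). Mmp9 rose 1.90-fold and Plaur 1.92-fold, and Mmp14 was 1.61-fold lower. Without WT 1, 4 of these genes rose, and 2 fell without Trem2 mutant 1. With library totals as the only scaling, 2 chemokine receptor and adhesion genes rose and 1 fell (median 0.17), 4 phagocytic receptors rose and 5 fell (median 0.03), and 6 matrix genes rose and 3 fell (median 0.14).

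More of the genes by which MDSCs suppress T cells rose than fell, which is not shown to be separate from the rise of granulocyte markers. Of 21 such effectors, 8 rose and 2 fell (11 rose and 2 fell adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.00787; adjusted p = 0.488 with an estimated correlation). Nt5e (CD73, which makes adenosine) rose 1.98-fold, and the NADPH oxidase genes Cybb and Ncf1 rose 2.22-fold and 1.95-fold. Wfdc17 was among the falls. The list call was lost without WT 1 (adjusted p = 0.0906), where 3 genes rose, and 1 gene fell without WT 2. Scaled by library totals alone, the median of the effectors was −0.03. Of 14 genes of alternative activation, 4 rose, 0 fell and 10 did not pass (5 rose and 1 fell adjusted over the list alone). Chil3, 21.5-fold higher, was named above among the largest rises, most of them neutrophil genes. The median of these 14 genes was 0.52 (camera adjusted p = 7.78e-04, and adjusted p = 0.431 with an estimated correlation). Without WT 1, 1 of them rose, and with library totals as the only scaling 3 rose and 1 fell (median 0.14).

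Lists of type I interferon, inflammatory and immediate early genes were higher. Of 26 type I interferon response genes, 14 rose and 1 fell (19 rose and 1 fell adjusted over the list alone), with a median of 0.51 (camera adjusted p = 2.33e-09; adjusted p = 0.323 with an estimated correlation). Cmpk2 rose 2.74-fold, the antiviral gene Rsad2 2.08-fold and Ifit1 1.98-fold. Without WT 1, 8 of them rose and 0 fell. Of 23 inflammatory cytokines and NF-kB targets, 10 rose and 0 fell (14 rose adjusted over the list alone), with a median of 0.85 (camera adjusted p = 2.42e-06; adjusted p = 0.488 with an estimated correlation). The chemokine genes Ccl7 and Cxcl3 rose 2.34-fold and 2.28-fold. Without WT 1, 2 of these genes rose, and without Trem2 mutant 1, 18 rose. Of 19 immediate early and heat shock genes, which respond to tissue digestion, 8 rose and 0 fell (12 rose adjusted over the list alone), with a median of 0.60 (camera adjusted p = 7.32e-05; adjusted p = 0.387 with an estimated correlation). Without WT 1, 0 of them rose, and 4 without WT 2 and 18 without Trem2 mutant 3. With library totals as the only scaling, 6 type I interferon genes rose and 1 fell (median 0.14), 11 inflammatory genes rose and 1 fell, and 5 immediate early genes rose and 1 fell. With DESeq2, 5 inflammatory genes rose.

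Cholesterol synthesis rose almost as a whole. Of 20 genes of the pathway, 17 rose and 0 fell (19 rose adjusted over the list alone), with a median of 1.14 (camera adjusted p = 1.06e-24; adjusted p = 0.387 with an estimated correlation). Cyp51 rose 3.59-fold, Msmo1 2.58-fold and Hmgcs1, which makes HMG-CoA, 2.22-fold. Lipid uptake and LXR target genes went both ways: 3 of 19 rose and 7 fell (4 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.316, not passed). Lrp1 was 1.61-fold lower and the cholesterol exporter gene Abcg1 1.44-fold lower, and both calls were lost without WT 1 (log2 fold changes −0.71 and −0.53, from −0.69 and −0.52) and without WT 2 (−0.67 and −0.52). The list had 0 falls and 1 rise without WT 1 and 0 falls without WT 2. Of 23 genes of the disease-associated microglia and lipid-associated macrophage programme, which depends on Trem2 in other tissues, 4 rose and 2 fell (10 rose and 5 fell adjusted over the list alone). That list did not pass (median 0.23, camera adjusted p = 0.250). Ccl6 rose 2.29-fold and Plin2 1.89-fold, and Gpnmb was 1.78-fold lower. In it 2 genes rose and 1 fell without WT 1, 1 fell without WT 2, and 9 rose and 4 fell without Trem2 mutant 3. Scaled by library totals alone, 3 genes of this programme rose and 8 fell, and 1 lipid uptake gene rose and 10 fell. With DESeq2, 4 lipid uptake genes fell.

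Among energy genes, the glycolysis list was higher and nuclear genes of oxidative phosphorylation were lower relative to other genes. Of 19 glycolysis genes, 11 rose and 0 fell (16 rose adjusted over the list alone), with the glucose transporter gene Slc2a3 at 3.92-fold (median 0.41, camera adjusted p = 2.01e-06; adjusted p = 0.488 with an estimated correlation). Without WT 1, 1 of them rose, and 4 without WT 2. Of 19 hypoxia response genes, 7 rose and 0 fell (10 rose adjusted over the list alone), with Egln3 1.84-fold higher (median 0.39, camera adjusted p = 3.29e-04; adjusted p = 0.481 with an estimated correlation). Without WT 1, 2 of them rose, and 11 without Trem2 mutant 3. Of 35 nuclear oxidative phosphorylation genes, 0 rose and 3 fell (7 fell adjusted over the list alone), with a median of −0.22 (camera adjusted p = 7.85e-04; adjusted p = 0.481 with an estimated correlation). None of them fell without WT 1 or without WT 2 (0 each), and 7 fell without Trem2 mutant 3. With library totals as the only scaling 28 of them fell, with upper-quartile scaling 7 and with limma-voom 1. With RLE scaling, DESeq2, no filter or noncoding classes left out, 0 fell. All 7 measured mitochondrially encoded genes rose (7 adjusted over the list alone), among them mt-Cytb at 1.80-fold (median 0.78, camera adjusted p = 2.01e-06; adjusted p = 0.424 with an estimated correlation). Without WT 1, 4 of them rose, and 4 without WT 2. With library totals as the only scaling, 1 glycolysis gene rose (median 0.03), 2 hypoxia genes rose and 1 fell (median 0.02), and 3 mitochondrially encoded genes rose (median 0.41). The mitochondrial chromosome held 2.18% and 2.43% of reads in WT 1 and WT 2, and 3.03% and 4.90% in Trem2 mutant 1 and Trem2 mutant 3.

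Of 16 unfolded protein and integrated stress response genes, 6 rose and 0 fell (8 rose adjusted over the list alone), with Xbp1 1.85-fold higher (median 0.37, camera adjusted p = 8.70e-04; adjusted p = 0.424 with an estimated correlation). Without WT 1, 1 of them rose, and with library totals as the only scaling 2 rose and the median was −0.0048. Of 36 cytosolic ribosomal protein genes, 1 rose and 3 fell (1 rose and 1 fell adjusted over the list alone), with Rplp0 1.57-fold higher (median −0.15, camera adjusted p = 0.0104; adjusted p = 0.458 with an estimated correlation). None of them fell without WT 1 or without WT 2 (0 each), 5 fell without Trem2 mutant 1 and 6 without Trem2 mutant 3. Scaled by library totals alone, 0 of them rose and 28 fell (median −0.52), and with RLE scaling 1 fell. Of 28 cell cycle genes, 5 rose and 0 fell (12 rose adjusted over the list alone), with a median of 0.74 (camera adjusted p = 0.00146; adjusted p = 0.652 with an estimated correlation). Their list call was lost without Trem2 mutant 1 (adjusted p = 0.199, 3 rose). In that list 0 genes rose without WT 1, 1 without WT 2 and 20 without Trem2 mutant 3, while 3 rose with DESeq2, and 6 rose and 2 fell with library totals as the only scaling.

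No measured gene next to Trem2 in its receptor family was called lower in the main fit. Treml4 had a log2 fold change of −0.37 (edgeR adjusted p = 0.340) and did not pass. Of 5 measured members of the Trem cluster on chromosome 17, 2 rose and 0 fell (3 rose adjusted over the list alone): Treml2 2.35-fold and Trem1, an amplifier of inflammation, 1.97-fold. The list was higher by camera (median 0.31, adjusted p = 0.00299; adjusted p = 0.387 with an estimated correlation), and its median was −0.06 with library totals as the only scaling, where 2 rose and 1 fell. Of 10 B and plasma cell markers, 0 rose and 2 fell (3 fell adjusted over the list alone), with a median of −0.68 (camera adjusted p = 0.00784; adjusted p = 0.387 with an estimated correlation). Igkc was 5.70-fold lower. Jchain had 12 and 11 reads in WT 1 and WT 2, and 0 and 2 in Trem2 mutant 1 and Trem2 mutant 3, a ratio of mutant to WT of 0.0903 (95% interval 0.0103 to 0.365, counting error only). Its call was lost without Trem2 mutant 1, where its log2 fold change was −2.46. Without Trem2 mutant 3, which leaves 0 mutant reads, its log2 fold change was −6.49. Among these markers 1 fell without WT 1, 1 without WT 2, 1 with DESeq2 and 1 with the stricter filter, and 6 fell with library totals as the only scaling.

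**Figure D2:**
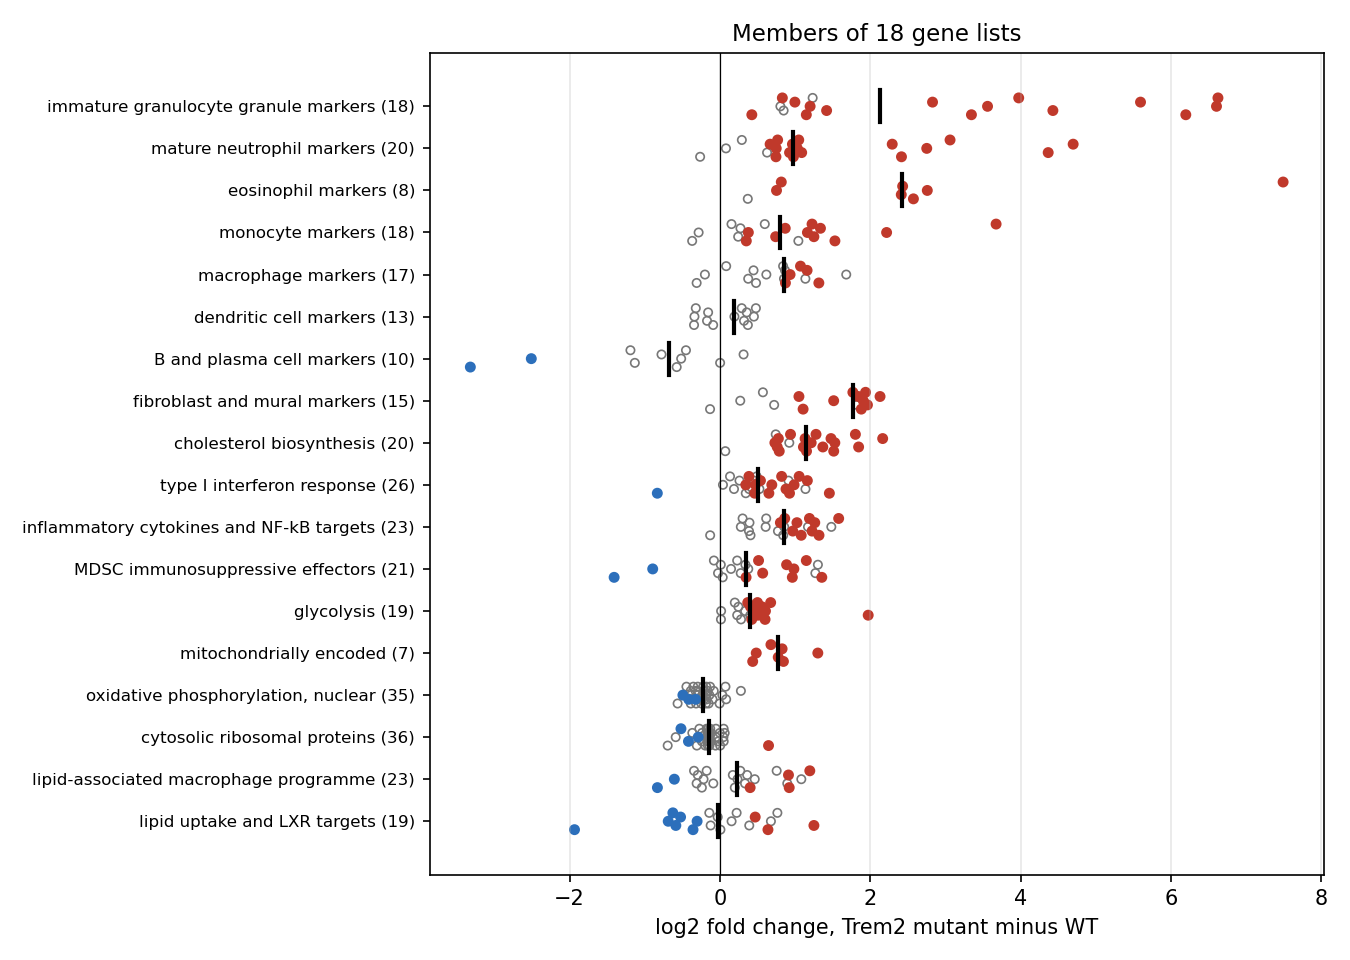
Log2 fold changes (Trem2 mutant minus WT) of the measured members of 18 gene lists, with the number of members in brackets and a black bar at each median. Filled red and blue points passed the test upward and downward, and open grey points did not; the eosinophil point at 7.49 is Ear1, which had 0 WT reads and is drawn at its fitted value. The granule, eosinophil and fibroblast lists have medians of 2.12, 2.42 and 1.77.

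In all, 42 lists were tested, of which 23 were higher and 3 lower with the preset correlation. The count was 0 in either direction with an estimated correlation, where camera uses the 2 residual degrees of freedom. Lists whose estimated correlation lay below the preset 0.01 lost their calls too, such as the type I interferon response (−0.0297). These losses alone therefore do not show that members vary together. With fry 2 lists passed, mature neutrophil markers (adjusted p = 0.0331) and the type I interferon response (adjusted p = 0.0212). The Pearson correlation across genes was 0.992 within WT and 0.989 within mutant, against 0.966 to 0.975 between genotypes. By the mean chi-square per gene of raw counts, Trem2 mutant 3 lay nearer to WT 1 and WT 2 (57.1 and 44.1) than to Trem2 mutant 1 (118). By the median over genes relative to sampling noise, the order was the other way (12.2 and 10.3 against 6.24). The mean can be set by a few genes with many reads. Gm42418 alone took 13.9% of reads in Trem2 mutant 1, against 0.418% in Trem2 mutant 3. The order by the mean therefore does not show that Trem2 mutant 3 was more like WT than like Trem2 mutant 1.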

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

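All alternatives here were planned except the bias-adjusted quasi-likelihood form, which was chosen after seeing the data. Trem2 stayed lower and past the threshold under every alternative run (log2 fold change −1.51 to −1.01). The count of genes higher, 1360, was 650 with library totals alone, 497 with at least a 2-fold change, and 489 to 2090 with 1 library left out, lowest without WT 1 and highest without Trem2 mutant 3. The count lower, 513, was 4365 with library totals alone, 205 with DESeq2, 95 with at least a 2-fold change, and 92 to 912 with 1 library left out, for the same libraries. With the bias-adjusted form, 1376 genes were higher and 514 lower. The lower mutant scaling factors (0.811 and 0.949, against 1.15 and 1.13 in WT) set the shift under library totals. With a WT library left out, the spread came from the mutant pair alone, and with a mutant library left out, from the WT pair alone. Relative to sampling noise the median was 6.24 within mutant and 2.01 within WT. Calls lost with 1 library left out can thus reflect a changed error term, and do not by themselves show dependence on that library. Beyond this, the cause of the moves was not tested. Of the 1873 calls, 30.0% were kept without WT 1, 42.1% without WT 2, 84.3% without Trem2 mutant 1, 93.3% without Trem2 mutant 3 and 64.6% with DESeq2. Lists higher numbered 0 with an estimated correlation and 2 with fry, and lists lower 0 with an estimated correlation and 0 with fry. Of the 188 genes taken by the naming rule, 148 were called; 62 of these calls were lost without WT 1, 38 without WT 2, 11 without Trem2 mutant 1, 6 without Trem2 mutant 3, 17 with DESeq2 and 27 with library totals alone, where 4 called genes also changed sign. The examples in the text lost fewer, having been picked with these values in view. With library totals alone, the sign of Eif2s3x reversed (−0.18) and Kdm5c, Kdm6a, Ddx3x and Rplp0 lost their calls. Lists reversed with library totals alone were TREM2-DAP12 signalling (adjusted p = 0.941), MHC class I (0.454, and 0.981 with upper-quartile scaling), apoptosis (0.836), dendritic cell (0.743) and platelet (0.949). With limma-voom the dendritic cell (0.962), mast cell (0.962) and sex-linked lists (0.362, its call lost) reversed, as did the dendritic cell list with no filter (0.995). With 1 library left out, camera adjusted p spanned 0.884 to 0.997 for MHC class I, 0.104 to 0.998 for apoptosis, 0.376 to 0.998 for dendritic cell, 0.469 to 0.884 for mast cell and 0.320 to 0.998 for platelet lists, each of which reversed at least once. Canonical histones spanned 2.01e-05 (lower, without Trem2 mutant 1) to 0.786. No paired analysis was possible because the columns carry numbers 1 and 2 for WT and 1 and 3 for the mutant, so that only number 1 is shared; the planned replicate block was not run. The planned omission of mutant replicate 2 was run on the column numbered 3. With 2 libraries per group, 68.4% of simulated 2-fold changes were recovered, so a gene that did not pass is not shown to be unchanged.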

Other observations

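Tests set only after the result was seen were those of scaling, of a uniform granulocyte rise (by pairs of markers, set after a test of medians did not decide), of mixed sexes, of 1 male share, of macrophage loss, and the counts, Fisher tests and windows near Trem2 by setting.

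TREM2-DAP12 signalling (median log2 fold change 0.19, camera adjusted p = 0.247), MHC class II (0.27, adjusted p = 0.438), MHC class I (0.01, adjusted p = 0.923) and fatty acid oxidation (0.15, adjusted p = 0.315) did not pass. The first of these passed with limma-voom (adjusted p = 0.0208; range 0.0208 to 0.941). The lysosome list did not pass (adjusted p = 0.550), with a median of 0.03 but a mean of −0.05 and a test direction of lower. Within the oxidative stress list, which did not pass (adjusted p = 0.0816), Gsr, encoding glutathione reductase, rose 4.15-fold, from 215 ± 6.92 to 890 ± 41.8 CPM (SD, n = 2 each, edgeR adjusted p = 3.01e-05). Pparg, a nuclear receptor that drives lipid storage, rose 2.95-fold. The interferon gamma list did not pass (camera adjusted p = 0.0764, and 0.488 with an estimated correlation). At the preset correlation it passed with limma-voom (camera adjusted p = 0.0332), with no filter (0.0417) and without Trem2 mutant 1. Apoptosis (adjusted p = 0.612), platelet (adjusted p = 0.642) and endothelial lists (adjusted p = 0.385) did not pass. Dendritic cell markers (adjusted p = 0.918) had a median of 0.19 and a mean of 0.08 but a test direction of lower, and mast cell markers (adjusted p = 0.939) a median of −0.15 but a mean of 0.04 and a test direction of higher. Canonical histones did not pass (camera adjusted p = 0.891, and 0.975 with an estimated correlation, which was 0.916). Their median CPM was 7.72 and 8.98 in WT 1 and WT 2, 12.8 in Trem2 mutant 1 and 6.77 in Trem2 mutant 3. By this median the mutant libraries lay on opposite sides of WT.

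Granulocyte genes rose in the mutant libraries. The tables argue against uneven scaling, since the lowest median of the granule list over 5 scalings was 1.73. A trend with GC content and gene length over all genes was argued against as the whole of it: correction moved 2193 of 14200 genes by more than 0.1, and the median stayed 2.10. One rise in granulocyte share lifting every marker alike was argued against, as 60.5% of 703 pairs of the 38 markers differed by more than 4 standard errors (51.2% without WT 2), though the list medians alone did not decide (two-sided permutation p = 0.0983). No value here separates more granulocytes of some kind, with part of these transcripts from other sorted cells, from higher expression per cell, and genotype itself stays untested; eosinophil markers rose as well, and so did fibroblast markers, which a CD45 gate should exclude.

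Mutant libraries held Xist and Y-linked transcripts together, at no fewer than 51 reads for any of Xist and 4 Y-linked genes. This is consistent with a mixture of female and male cells, for example female donor cells and male recipient cells, a hypothesis since donor sex is not given in the sources used here. X-linked genes that escape silencing had a median log2 fold change of 0.52, which also goes with female cells: Kdm6a (0.69) and Kdm5c (0.63) were called, though not with library totals alone, the call of Ddx3x (0.41) was lost without WT 1 (0.34), without WT 2 (0.48), with upper-quartile scaling (0.37) and with library totals alone (0.05), and Eif2s3x did not pass (0.19). A single male share setting every Y-linked gene alike was argued against, because Kdm5d and Ddx3y differed by 13.3 standard errors. If male cells were the recipient's, Y-linked genes that differ between cell types could fall unequally, so donor sex, recipient cells and genotype remain entangled in these 4 libraries.

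Trem2 was lower, and so were 10 of 88 tested genes within 5 Mb of it (odds ratio 3.48, two-sided Fisher exact p = 0.00123; 13 were higher, p = 0.101), among them Abcc10 (2.21-fold) and Trerf1 (1.85-fold). A fall of macrophages as a whole was argued against as the source. The macrophage markers had a median log2 fold change of 0.85 (0.54 without WT 1, 0.57 without Trem2 mutant 1, 0.46 with library totals alone). All 17 lay above Trem2 in each fit run. These markers cannot show whether a part of the macrophages with more Trem2 became fewer, which was not tested. The odds ratio was 1.85 (95% interval 0.0459 to 10.9, 1 gene; Abcc10 at −1.01, adjusted p = 0.0515) without WT 1, 2.60 (0.307 to 9.89, 2 genes) without WT 2, 2.28 (0.948 to 4.75, 8 genes) without Trem2 mutant 1, 2.11 (1.01 to 4.00, 11 genes) without Trem2 mutant 3, 1.61 (0.191 to 6.09, 2 genes) with DESeq2 and 1.43 (0.899 to 2.23, 34 genes) with library totals alone. Clusters of this density all over the genome stay open: 0.112% of 9865 other windows had as high a share of lower calls in the main fit, but 21.6% without WT 1, 11.8% without WT 2, 5.48% without Trem2 mutant 1, 2.24% without Trem2 mutant 3, 19.5% with DESeq2 and 13.1% with library totals alone. The share of windows was 0.0728% with the stricter filter, 0.116% with noncoding classes left out and 0.253% with upper-quartile scaling. It was 0.72% with limma-voom, 1.23% with no filter and 2.85% with RLE scaling. In these fits the odds ratio was 2.53 to 3.51. A change over the region stays open, as these values moved with the fit. Flanking chromosome 17 sequence that differs between the mutant and WT mice, a candidate explanation, was not tested by these counts. The share of Trem2 reads from recipient cells, which the gate did not separate, is not known.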
